A study of Mus musculus with 2 samples.

How the data were processed

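Messenger RNA was measured by RNA sequencing in MIN6 cells, an insulin-secreting mouse insulinoma line used as a model of the pancreatic beta cell. Per the labels' protocols, the cells grew in medium with 25 mM glucose and 15% serum, were transfected in 3.5 cm dishes with 4 ug of plasmid and 4.8 ul of Lipofectamine 2000, and total RNA was extracted with Trizol for Illumina libraries. The labels give 1 sample transfected with a control vector and 1 transfected with an expression vector for the glucocorticoid receptor (GR, gene Nr3c1). The species and form of the GR cDNA, the time from transfection to harvest and any added glucocorticoid are not given in the sources used here, and neither are the aligner, the counting tool, strand handling and the genome build.

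Each library has a column of scaled read counts per gene, a normalized signal that the authors deposited for 21542 genes. Every value was a whole multiple of 1 step per library (100% of values within 0.01 reads), with a count of 0 written as a number close to 0, so whole reads could be recovered by dividing by the step. The recovered reads came to 18537326 for the control vector and 18525668 for the GR vector. There were 20749 genes with at least 1 read in the control library and 20737 in the GR library, and 11073 and 11060 genes with at least 100 reads. The lowest total of a gene over both libraries was 2 reads. No column of values belonged to a sample outside the series.

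The same table holds a log2 fold change of the GR vector over the control vector that the authors deposited, with an unadjusted p-value and an adjusted p-value that the authors deposited beside it. The submitters' processing notes name DESeq2 1.10.1. The deposited p-values and fold changes were compared here with an exact test of edgeR 4.0.16 on the recovered reads, with TMM scaling (factors 1.00 for both libraries), 1 library per group and a preset dispersion of 0.04, which is a coefficient of variation of 20%. They differed by at most 4.5e-08 in p and 4.9e-08 in log2 fold change. The spread behind these p-values is therefore a preset value and was not measured between replicates. The deposited adjusted p differed from a Benjamini-Hochberg adjustment over all genes by at most 0.00019. A second table that the authors deposited lists 233 genes, which are exactly those with an unadjusted p under 0.05 and an absolute log2 fold change over 1.

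The authors also deposited a gene set enrichment report in the layout of GSEA, with an enrichment score, a normalized enrichment score, nominal p-values and q-values for 307 sets, and the members of 1 autophagy set with the ratio that ranked each gene. That deposited ratio equalled the recovered reads of the GR library over those of the control library to within 9.4e-08. The version of GSEA, the number of permutations and the kind of permutation are not given in the sources used here.

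Gene coordinates are those of the deposited table. Of its gene identifiers, 21533 occur in GENCODE M21 (GRCm38), 97.0% of these with the same chromosome, start and end and 99.3% with the same symbol. That annotation was used for transcript GC content and for the share of each gene's 31-mers (stretches of 31 bases) that also occur in another annotated gene. A gene with 25% or more of its 31-mers shared can lose or gain reads by the way reads that match several places are handled. The share is taken over all annotated transcripts of a gene, so a gene under 25% can be affected too. The pseudogene Gm10241 shares 100% of its 31-mers with Sumo2, whose own share is 22.5%.

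The groups compared were the GR vector and the control vector. The main count of genes took the authors' adjusted p under 0.05, split by the sign of their log2 fold change. The design had foreseen a test of replicate counts if the tables held any, and with 1 library per group none could be run. Folds given here were computed from the recovered reads and the TMM-scaled library sizes, with exact 95% Clopper-Pearson intervals. These intervals, and an exact two-sided binomial test of the reads with Benjamini-Hochberg adjustment over all genes (the library test below), cover counting error only. A test on the reads of 2 libraries compares those libraries, not the conditions. For 29 gene lists fixed before the data were examined, the median deposited log2 fold change was set beside 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes these libraries and carries no p. Reads per gene limit the precision, and a gene at 0 reads may have up to 3 by counting error.

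Genes were named by a rule written before the data were examined. Nr3c1 came first, then the 10 largest increases and 10 largest decreases past the authors' adjusted p among genes with a mean of at least 50 reads, leaving out names that start with Gm and digits, end in Rik or lack a symbol. From each list the rule took the 2 largest changes past that threshold and the 2 members with the most reads, and it took the measured leading members of the autophagy set and the 10 sets with the highest normalized score. It gave Gapdh and 2810047C21Rik1 beyond Nr3c1. Other genes named here were chosen after their values were seen, and 1 list member that the rule takes is not reported here.

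Alternatives fixed beforehand were a stricter adjusted p of 0.01, a minimum absolute log2 fold change of 1, a minimum mean of 50 reads, a repeated adjustment, centring on the median gene, pseudocounts of 0.1, 1 and 5, means in place of medians, and other thresholds and set sizes for the enrichment report. Alternatives chosen after seeing the data were the library test, edgeR's exact test with dispersions of 0.01, 0.16 and 0.0012 (the scatter between the 2 libraries over 11070 genes), the deposited list, the genes under 25% of shared 31-mers, and removal of the GC trend. The exact test with the preset dispersion was tested on simulated libraries of 21542 genes with the scatter of these 2 libraries. It recovered 0% of 50 genes changed 1.5-fold, 0% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 0 false calls. The changed genes all had a mean of at least 100 reads, so recovery at lower depth was not tested. The library test on simulated libraries called 196 of 200 changed genes and also 728 unchanged genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.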

Results

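RNA sequencing profiled MIN6 mouse insulinoma cells carrying either a control vector or a GR expression vector, with 1 library of each. The control library held 18537326 reads over genes and the GR library 18525668. There are no replicates, so no difference below has a replicate check. Among 11070 genes with a mean of at least 100 reads, 95.0% lay within 1.2-fold of each other in the 2 libraries. Both libraries held transcripts of the beta cell. Ins2 (insulin 2) took 2.20% of the reads with the control vector and 2.01% with the GR vector. Iapp (islet amyloid polypeptide, secreted together with insulin) took 1.53% and 1.48%. The 10 most read genes together took 6.92% and 6.70%.

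The comparison asks what a raised level of GR, the nuclear receptor for glucocorticoids, does to the transcripts of these cells. Nr3c1, the gene of the receptor (ENSMUSG00000024431, chromosome 18, 39410545 to 39491301, minus strand), was the targeted gene and had 2645 reads with the control vector and 5202 with the GR vector. This is a fold of 1.97 (95% interval 1.88 to 2.07). The gene counts do not separate transcripts of the vector from those of the cells' own gene, and the species and form of the cDNA are not given in the sources used here. Among the 4867 genes with a mean of at least 1000 reads it had the 2nd highest fold, after Gapdh. In the authors' deposited table its log2 fold change was 0.98, with an unadjusted p of 0.0183 and an adjusted p of 1, so it did not pass the adjusted threshold, and its size left it out of the deposited list of 233 genes. The exact test with the preset dispersion, whose p-values equal the deposited ones, recovered 0% of 2-fold changes in simulated libraries. Missing the adjusted threshold therefore says little about Nr3c1. Only 0.13% of the 31-mers of Nr3c1 occur in another annotated gene.

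In the authors' deposited table, whose p-values equal those of edgeR's exact test with a preset dispersion, 4 genes passed an adjusted p under 0.05, 2 higher and 2 lower with the GR vector. Gapdh, the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase (ENSMUSG00000057666, chromosome 6, 125161715 to 125166467), rose from 206 to 3439 reads, a fold of 16.7 (95% interval 14.5 to 19.4). Its log2 fold change in the authors' deposited table was 4.06, with an adjusted p of 1.57e-13. The pseudogene 2810047C21Rik1 (chromosome 7, 8086326 to 8093041) rose from 15 to 103 reads, with a log2 fold change of 2.77 and an adjusted p of 0.00617 in the authors' deposited table. The pseudogene Gm20482 (chromosome 7, 8855847 to 8862851) fell from 73 to 2 reads and the protein-coding gene Gm14419 (chromosome 2, 177000956 to 177012787) from 53 to 6. Their adjusted p in the authors' deposited table was 2.69e-06 and 0.0307. All 4 share 25% or more of their 31-mers with other genes (28.1% for Gapdh, 100% for 2810047C21Rik1, 86.8% for Gm20482 and 96.4% for Gm14419), so their counts are uncertain. With a preset dispersion of 0.16 in place of 0.04, 0 genes passed.

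Below the threshold, the next lowest adjusted p in the authors' deposited table was 0.145, for Sumo2, a ubiquitin-like modifier, which had 2087 and 609 reads (fold 0.293, 95% interval 0.267 to 0.320; 22.5% of its 31-mers shared). Rps27a, a ribosomal protein made as a fusion with ubiquitin, had 3263 and 1463 reads (fold 0.450, 0.422 to 0.478; 28.5% shared). Gapdh, Nr3c1, Sumo2, Rps27a and the ribosomal protein gene Rpl21 were the 5 genes with a mean of at least 1000 reads whose absolute log2 fold change reached 0.5. The deposited list of 233 genes, taken at an unadjusted p, held 115 higher and 118 lower genes. Its genes were sparsely read: 214 had a mean under 50 reads, 75 had 0 reads in 1 library and the median was 8 reads.

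**Figure D1:**
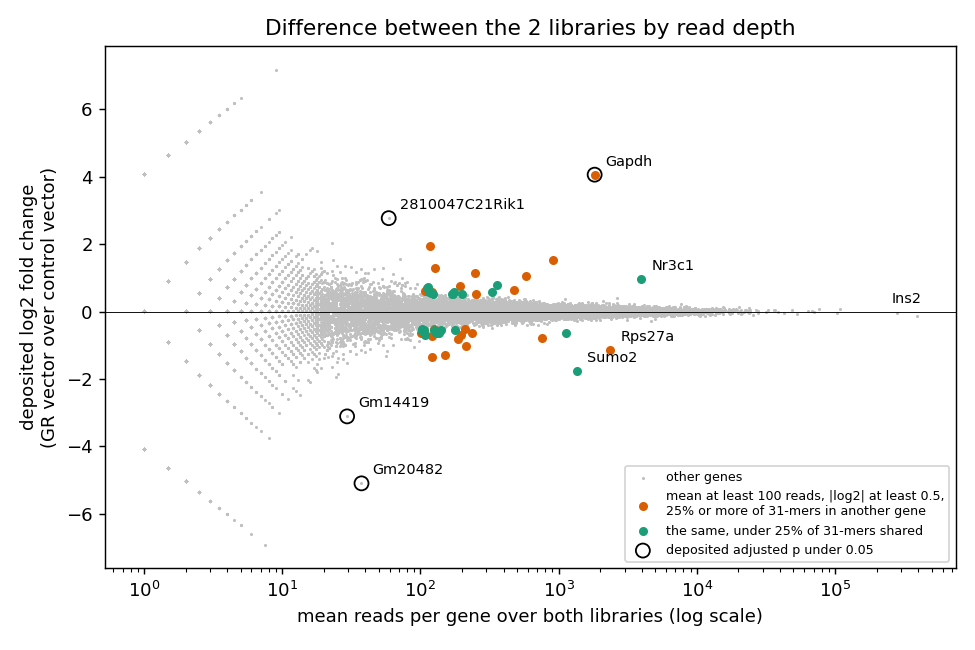
Deposited log2 fold change of the GR vector over the control vector (vertical axis) against the mean reads per gene over both libraries (horizontal axis, log scale), 1 point per gene and 1 library per group. Orange and green points have a mean of at least 100 reads and an absolute log2 fold change of at least 0.5, with 25% or more (orange) or under 25% (green) of their 31-mers in another gene; circles mark the 4 genes with a deposited adjusted p under 0.05. Nr3c1 stands at 0.98 and Gapdh at 4.06.

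The median of the genes known to respond to GR lay close to 0, with members on both sides. Over 31 measured glucocorticoid target genes, the median log2 fold change from the authors' deposited table was -0.0033, at the 38.8th percentile of random lists (0.01 and the 71.1st percentile with the GC trend removed), with 15 members above 0 and 16 below. Members with a mean of at least 50 reads ran from -0.51 for Arrdc2 (76 and 53 reads) to 0.35 for Nfkbia, an inhibitor of NF-kappaB (240 and 306 reads), in the authors' deposited table, and neither passed the library test. Fkbp5, a co-chaperone of the receptor that glucocorticoids induce in many tissues, had 2580 and 2714 reads (fold 1.05, 95% interval 0.999 to 1.11). Tsc22d3, which encodes the leucine zipper GILZ, had 990 and 906 reads (fold 0.918, 0.838 to 1.01), Per1 895 and 915, and Klf9 1803 and 1824. Of the most abundant members, the metallothionein gene Mt1 had 6910 and 6320 reads (fold 0.917, 0.886 to 0.949), the 1 member past the library test, and Cdkn1a 7394 and 6995. In the list of steroid receptors and glucocorticoid handling (15 measured, median 0.05, 89.3rd percentile, from the authors' deposited table), Nr3c1 was the only member past the library test. The co-repressor gene Ncor1 had a fold of 1.04. Hsd11b1, the enzyme that regenerates active glucocorticoid, had 0 reads with the control vector and 6 with the GR vector.

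Beta cell genes had a median close to 0, with 20 members above 0 and 17 below. Over 37 measured identity and function genes the median log2 fold change from the authors' deposited table was 0.01, at the 55.4th percentile, and 7 members were higher and 5 lower in the library test. Ins2 had 407986 and 373033 reads (fold 0.917, 95% interval 0.913 to 0.921) and Iapp 283796 and 273874 (fold 0.968, 0.963 to 0.973). With the trends of gene length and GC content removed, the log2 fold change of Ins2 went from -0.13 in the authors' deposited table to -0.05. The difference of Iapp grew. The transcription factors Pdx1 and Mafa had folds of 1.04 and 1.02, and the glucose transporter gene Slc2a2 1.02. Over 20 insulin exocytosis genes the median in the authors' deposited table was -0.03 (5.92nd percentile, 34.2nd with the GC trend removed), with 8 above 0 and 12 below. Cplx2 had a fold of 1.02 and the granule protein gene Sytl4 one of 1.05. Log2 fold changes of members with a mean of at least 50 reads ran from -0.27 for Stx1a to 0.15 for Syt5 in the authors' deposited table. Over 14 genes normally kept low in beta cells the median was -0.0030 (44.3rd percentile); Ldha, lactate dehydrogenase A, had 907 and 1085 reads and differed between the libraries, while Hk1 and Igfbp4 had folds of 0.982 and 0.974.

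Autophagy genes, the set for which member values were deposited, likewise had a median near 0 over members that went both ways. Over 51 measured genes of the core machinery the median log2 fold change from the authors' deposited table was 0.02, at the 79.7th percentile, with 30 members above 0 and 21 below. Atg10, an E2-like enzyme of the Atg12 conjugation system, had 181 and 252 reads (fold 1.40, 95% interval 1.15 to 1.70) and was the 1 member past the library test. The cargo receptor gene Sqstm1 had 14770 and 14327 reads (fold 0.973, 0.951 to 0.995), Gabarap 5510 and 5422, Atg5 805 and 809, and Becn1 1873 and 1822. Over 33 lysosome genes the median in the authors' deposited table was -0.04, at the 0.17th percentile, with 12 members above 0 and 21 below. There Psap (prosaposin) had 28344 and 27188 reads (fold 0.962), Lamp1 14523 and 14076 (fold 0.972), Ctsd (cathepsin D) a fold of 0.911 and Lamp2 one of 1.07. With the GC trend removed, the lysosome median lay at the 3.69th percentile, inside the central 95%. The folds of single members are given without that correction.

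**Figure D2:**
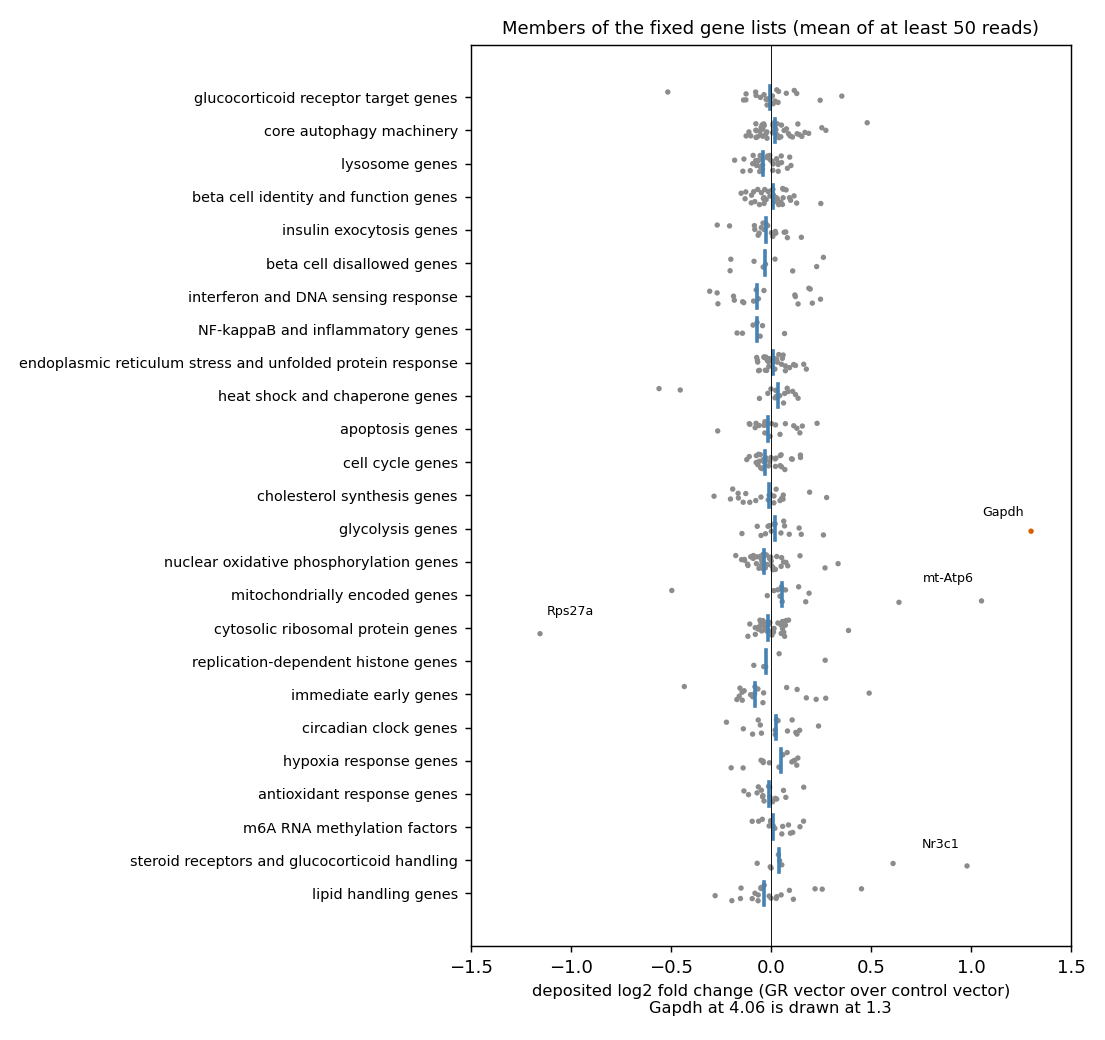
Deposited log2 fold change (horizontal axis) of members with a mean of at least 50 reads, for the fixed lists with at least 5 such members (rows); grey points are genes, blue bars the medians, and Gapdh, at 4.06, is drawn in orange at the edge. The medians of the glucocorticoid target and core autophagy genes lie next to 0, while Nr3c1, Gapdh, mt-Atp6 and Rps27a stand apart from their lists.

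The authors' deposited enrichment report holds 307 gene sets, all with a positive enrichment score between 0.433 and 0.704. It is titled for the GR library, and none titled for the control library was used here. The shared sign thus says nothing about sets outside the report. In that deposited report 0 sets had an FDR q under 0.25, the lowest q was 0.877 and the lowest family-wise p was 0.5. The nominal p took only the values 0, for 159 sets, and 0.5, for 148 sets. With 1 library per group and p-values this coarse, the report could not resolve sets at such thresholds. That 0 sets passed is therefore no evidence against any of them. By normalized score the first were mucin type O-glycan biosynthesis (1.06), vitamin digestion and absorption (1.06), ABC transporters (1.05) and the autophagy set (1.05), all in the authors' deposited report. After them came GPI-anchor biosynthesis (1.05), renal cell carcinoma (1.04), chondroitin and dermatan sulfate biosynthesis (1.04), TGF-beta signalling (1.04), heparan sulfate and heparin biosynthesis (1.04) and phototransduction (1.04).

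The autophagy set had 32 genes, an enrichment score of 0.699 and an FDR q of 1.00 in the authors' deposited report, 4th by normalized score and 2nd by enrichment score. All 31 of its measured members were marked as leading the score, of which 16 had a ratio of GR to control reads above 1 and 15 below 1. Folds ran from 0.933 for Atg3 to 1.40 for Atg10, and the median log2 fold change in the authors' deposited table was 0.01, at the 64.7th percentile of random lists. After Atg10 the highest were Atg4a (1.21), Atg4c (1.19), Igbp1 (1.13), Atg12 (987 and 1078 reads) and Wipi1 (1.06). Ppp2cb, Mtor, Gabarapl2, Ppp2ca and Atg16l1 lay at 1.02, and Rptor, Atg101, Atg9a, Atg5 and Pik3c3 at 1.01. Below 1 were Gabarap and Gabarapl1 (0.987 and 0.986), Atg4b (0.983), Pik3r4 (0.977), Becn1 (0.976), Atg9b (0.972), Atg2a (0.968), Ulk2 (0.967), Atg4d (0.964), Atg2b (0.954), Wipi2 (0.951), Atg13 (0.950), Atg7 and Mlst8 (both 0.949).

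**Figure D3:**
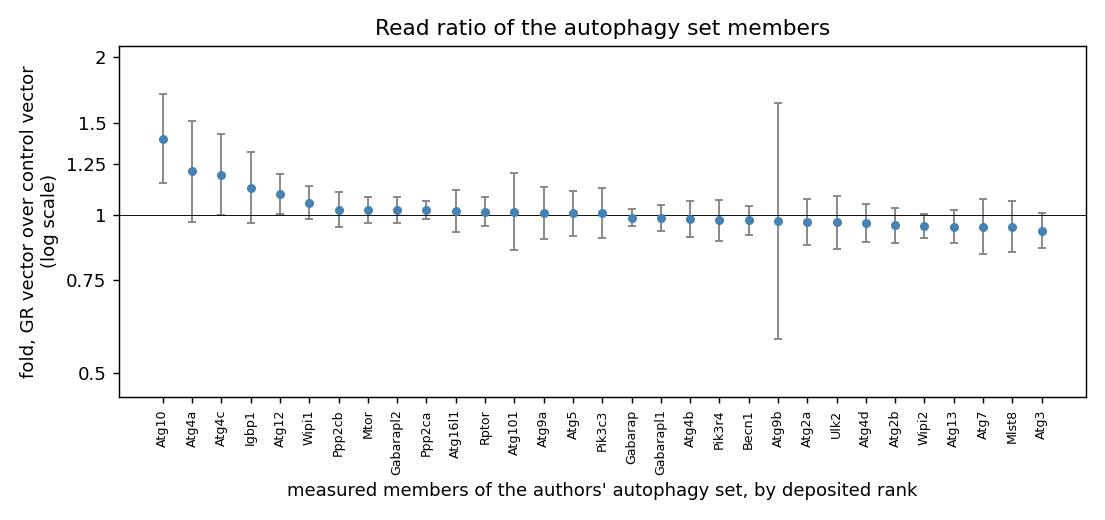
Fold of the GR vector over the control vector (vertical axis, log scale) for the 31 measured members of the deposited autophagy set, in order of their deposited rank (horizontal axis), with exact 95% intervals for counting error, 1 library per group. Points run from 1.40 for Atg10 to 0.933 for Atg3, with 16 above and 15 below 1 as read ratios.

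Stress and inflammatory lists held no member past the authors' adjusted p, which says little, since that test recovered 0% of 2-fold changes in simulated libraries. The library test called Hsp90b1 (endoplasmic reticulum stress), Hsp90aa1 and Ptges3 (heat shock) and Bcl2l11 (apoptosis) higher in the GR library, and no member of these lists lower. The medians from the authors' deposited table were 0.01 for endoplasmic reticulum stress (54.4th percentile; Hspa5 fold 1.04, Sesn2 0.977), 0.03 for heat shock and chaperone genes (80.0th; Hsp90aa1 1.05, Hsp90ab1 1.00) and -0.02 for apoptosis (18.9th; Bax 0.930, Mcl1 1.02). They were -0.05 for interferon and DNA sensing genes (17.7th; Usp18 0.950, Ifi27 0.907), -0.10 for NF-kappaB and inflammatory genes (5.08th; Sod2 0.953, Csf1 1.05) and -0.01 for antioxidant genes (25.0th; Txnrd1 1.02) in the authors' deposited table. Immediate early genes had a median of -0.08 in the authors' deposited table (2.39th percentile, 11.7th with the GC trend removed), with Jun at a fold of 0.975 and Jund at 0.945.

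Among metabolic lists, glycolysis (17 measured) had a median of 0.02 in the authors' deposited table, at the 72.6th percentile; with the GC trend removed it was 0.05, at the 99.8th, outside the central 95%. Gapdh was its 1 member past the adjusted p, over all genes and also adjusted over the list alone. In the list 11 members lay above 0 and 6 below, some of them next to 0. The library test called 4 members higher, Gapdh among them, and 0 lower. The more abundant Pkm and Eno1 had folds of 0.990 and 1.01, and Aldoa had 7752 and 8525 reads. Nuclear genes of oxidative phosphorylation (46 measured) had a median of -0.03, at the 0.27th percentile, from the authors' deposited table, with Atp5a1 at 1.00 and Atp5b at 0.979. The 15 mitochondrially encoded genes had a median of 0.06 (97.4th percentile) in the authors' deposited table, which turned to -0.02 (9.24th percentile) with the GC trend removed. The abundant mt-Co1 and mt-Cytb had folds of 1.05 and 1.01, and mt-Atp6 had 381 and 788 reads (fold 2.07, 95% interval 1.83 to 2.35) with 99.5% of its 31-mers shared. Other medians in the authors' deposited table were -0.01 for cholesterol synthesis (35.8th; Sqle 1.04, Srebf2 0.930), -0.02 for lipid handling (17.0th; Scd2 1.02, Fads1 0.977) and 0.06 for hypoxia genes (95.4th; Vegfa 0.973, Ndrg1 0.974). Mlxipl, the glucose-sensing transcription factor ChREBP, had 5112 and 4203 reads (fold 0.825, 0.791 to 0.859) and differed between the libraries.

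Growth-related lists had medians as close to 0, but single members stood apart. Cytosolic ribosomal protein genes ran from a log2 fold change of -1.15 for Rps27a to 0.39 for Rps13 (2313 and 3018 reads) in the authors' deposited table. Of that list, 17 members lay above 0 and 23 below. Cell cycle genes (34 measured) had a median of -0.03 in the authors' deposited table, at the 1.57th percentile and at the 5.16th with the GC trend removed, with Top2a at a fold of 1.04, Mki67 at 1.07 and Mcm2 at 0.965. Cytosolic ribosomal protein genes had a median of -0.02 (3.51st; Rpl4 1.05, Rplp0 0.959) and replication-dependent histone genes of -0.04 (34.5th; Hist1h1c 0.982, Hist1h2bc 0.943) in the authors' deposited table. Circadian clock genes had a median of 0.02 (75.2nd, 97.6th with the GC trend removed; Clock with 2722 and 2999 reads, Nr1d2 at a fold of 1.09) and m6A RNA methylation factors of 0.0085 (56.6th; Hnrnpa2b1 1.01, Hnrnpc 1.06), also from the authors' deposited table. Fto, an m6A demethylase, had 1472 and 1459 reads.

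Of the markers of other cell types, Ttr, Dpp4 and Krt7 had over 1000 reads in each library, and most others had few. Markers of alpha, delta and PP cells (9 measured) had a median of 0.22 in the authors' deposited table, at the 97.6th percentile (97.0th with the GC trend removed, inside the central 95%), with 0 members past the library test. Glucagon (Gcg) had 537 and 623 reads (fold 1.16, 95% interval 1.03 to 1.31), somatostatin (Sst) 92 and 114, Ttr 5187 and 5164 (fold 0.998) and Dpp4 2907 and 3138 (fold 1.08). Exocrine markers had a median of 0.0039 (53.2nd) in the authors' deposited table; the duct keratin gene Krt7, with 2429 and 2166 reads (fold 0.894, 0.844 to 0.948), was lower in the library test, and Spp1 had 327 and 338 reads. Fibroblast and endothelial markers had a median of -0.59 (6.63rd; Col1a1 55 and 68 reads, Thy1 12 and 13) over members with a median of 8.75 reads, and the 1 member with a mean of at least 50 reads, Col1a1, stood at 0.31 in the authors' deposited table. Immune markers had a median of -0.19 (23.8th; Cd68 24 and 21 reads, C1qa 186 and 192) in the authors' deposited table. In 10 of the 29 lists the median and the mean differed in sign, among them the glucocorticoid targets (mean 0.02).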

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

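The library test, the other dispersions, the deposited list, the limit on shared 31-mers and the GC correction were chosen after the data were seen. The 4 genes past the authors' adjusted p, 2 higher and 2 lower, stayed 4 with a minimum absolute log2 fold change of 1, with a repeated Benjamini-Hochberg adjustment and with centring. At an adjusted p under 0.01, 3 genes were left, 2 higher and 1 lower. With a mean of at least 50 reads, 2 genes were left, both higher, and 0 lower. A preset dispersion of 0.01 gave 16 genes (10 higher, 6 lower), 0.16 gave 0 (0 higher, 0 lower), and the scatter between the 2 libraries gave 36 (17 higher, 19 lower). The library test gave 585 genes (340 higher, 245 lower) and the deposited list 233 (115 higher, 118 lower). Among genes under 25% of shared 31-mers the count was 0 (0 higher, 0 lower), since all 4 lie above that limit. The dispersion settings differ only in the spread they preset, which 1 library per group cannot measure; for the other shifts the cause was not tested. The number of lists outside the central 95% of random lists was 5 as reported, under each pseudocount and with centring, 4 under means, 6 with members of at least 50 reads, and 3 with the GC trend removed: nuclear oxidative phosphorylation (0.050th percentile), glycolysis (99.8th) and circadian clock genes (97.6th). With the GC trend removed, the median of 7 lists changed sign, the glucocorticoid targets (-0.0033 to 0.01) and the mitochondrially encoded genes (0.06 to -0.02) among them. The correction of the mitochondrially encoded genes is uncertain, since their GC content lies at the low end of the trend. The medians of the glucocorticoid target and core autophagy lists stayed within counting error under each alternative run. Over all 29 lists, 191 recomputed medians did so and 12 did not, 10 of them under means in place of medians. Pseudocounts and centring, which moved most medians little, make up most of the 191, so this tally says little about stability. No set of the enrichment report passed at q under 0.25, at q under 0.05, at a family-wise p under 0.05 or among sets of at least 30 genes. The nominal p in that report was only 0 or 0.5 and the lowest family-wise p 0.5. These alternatives could hardly differ, so the same count under each shows no stability. No paired analysis was possible because each group has 1 library. Leaving out replicates, a replicate block, DESeq2 and a refit without a low-count filter had been planned only for replicate counts and were not run. Depth limits genes of few reads most: 214 of the 233 listed genes have a mean under 50 reads.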

Other observations

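The tests of counting noise, of the 31-mers of Nr3c1, of the genes left after each trend was removed, of the shift of the autophagy genes and of the number of high sets were chosen after the result was seen, as was the choice of single pairs named below. The bounds for the other tests were set first; before the test of closest copies was run, the opposite differences of the pseudogenes Gm20482 and 2810047C21Rik1, which lie outside the genes it covers, had been seen.

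Gapdh had 206 reads in the control library, against a glycolysis list median of 2480. Its 3439 reads in the GR library lay above that median and near Gpi1 (3529 and 3690) and Pfkp (3596 and 3749). In both libraries it stayed below Aldoa (7752 and 8525). The level of Gapdh in the GR library thus lay between the list median and the levels of Gpi1, Pfkp and Aldoa. Its level in the control library lay far below that median. Which of these levels is usual for Gapdh in these cells was not tested. Among beta cell genes, Ins1 had a fold of 0.956, Chga 0.975 and Abcc8, the sulfonylurea receptor, 0.935, while Scg2 (1.04), Scg5 (1.09), Pcsk1 (1.08) and Ero1lb (1.07) were higher in the GR library. Prlr, the prolactin receptor, had 1714 and 2032 reads, a fold of 1.19 (95% interval 1.11 to 1.27). Apart from Gpi1 and Pfkp, each of these passed the library test, which compares the libraries only. Folds of single genes carry the trends with length and GC content: with both removed, the log2 fold change of the authors' deposited table went from -0.13 to -0.05 for Ins2, from -0.12 to -0.07 for Mt1, from -0.10 to -0.06 for Abcc8, from 0.12 to 0.06 for Pcsk1, from 0.09 to 0.06 for Ero1lb and from 0.25 to 0.15 for Prlr. It hardly moved for Ins1 (-0.07 to -0.07), Scg2 (0.06 to 0.05) and Scg5 (0.13 to 0.13), grew for Iapp (-0.05 to -0.09) and crossed 0 for Chga (-0.04 to 0.03) from its value in the authors' deposited table.

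With Nr3c1 left out, 47 genes with a mean of at least 100 reads had an absolute log2 fold change of at least 0.5. Of these, 55.3% had 25% or more of their 31-mers in another gene, against a median of 17.0% and an upper bound of the central 95% of 27.7% in expression-matched draws, so the handling of reads that match several copies is a candidate explanation for part of them, and 0.13% for Nr3c1 argues against it there. Counting noise does not account for the 35 genes (74.5%) past the library test, and cannot be told apart from a difference for the other 12, whose reads are too few. That test covers counting error only, and fewer of the 35 passed when the scatter between the 2 libraries was allowed for. A trade of reads between copies was tested through the closest measured copy. It moved the opposite way for 14 (53.8%) of the 26 genes with shared 31-mers. This lay between the bounds of 50%, about what copies with no link would give, and 75% set beforehand. Only 4 of the 14 copies passed the library test and 3 of the 26 pairs overlapped, so that test decided nothing. Some closest copies shared little, such as Nat8f1 with 0.684% of the 31-mers of Nat8f4. Among the 4, Gm8121 with Immp1l summed to 580 and 576 reads and Gm8116 with Carnmt1 to 508 and 512. Gm10241 with Sumo2, which holds 100% of its 31-mers, summed to 2555 and 1966, and Gm12411 with Rpl21 to 1438 and 1075. Gapdh with Gm7336 summed to 495 and 3743. Each sum takes in 1 copy only, so an unequal sum does not exclude a trade with other copies. An effect of GR on the genes with few shared 31-mers, such as Uchl3 (261 and 453 reads), stays open and untested, with 1 library per group.

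Beyond those genes, 482 genes with a mean of at least 100 reads differed in the library test by a median of 11.1%, 289 higher and 193 lower with the GR vector. Across 11062 genes, which are not independent replicates, the log2 fold change fell with GC content (Spearman rho -0.38), from a median of 0.07 over genes around 40.8% GC to -0.05 over genes around 59.5% GC. With that trend removed 31.7% of the 482 genes were still called, below the 50% bound set beforehand. A GC trend between the libraries is thus a candidate explanation for most of them. The smooth trend removed here does not account for the 153 still called, which differed beyond counting error. Removing the length trend left 81.5%, between the bounds of 50% and 90% set beforehand, and the 393 genes still called argue against length as the whole cause. Scatter between the libraries can also leave genes called, since the library test called 728 unchanged genes in simulated libraries. A response to GR is open for the rest and was not tested, since the vector and the library cannot be separated with 1 library each.

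The autophagy set ranked 4th of 307 by normalized score, although 16 of its 31 measured members had a read ratio above 1 and 15 below. Their median log2 fold change lay at the 64.7th percentile of random lists, which decides nothing over members that go both ways, so higher expression of some of them, such as Atg10 (1.40), stays open. The deposited ranking holds about 54530 genes, while 19944 had reads in both libraries, and random expression-matched sets scored a median of 0.660 under that ranking against 0.700 for the autophagy set. Its score was at the 99.7th percentile of 10000 such sets, so the ranking alone does not give the whole of it. The running score was -0.033 at Atg10, with the highest ratio, and peaked at 0.699 at Atg3, with the lowest (0.930). The score thus reflects that no measured member fell far below a ratio of 1, and does not show that members were higher. If the share of random sets scoring as high held for each set, 1.04 of 307 sets would score as far up with no effect. The draws matched the size and expression of the autophagy set only, so the share for the other sets is not known. They used the enrichment score, by which the set ranked 2nd. Being 1 of the highest of many sets thus stays a candidate explanation for the remainder.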
